A study of Mus musculus with 6 samples.

How the data were processed

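NRF2, the transcription factor encoded by Nfe2l2 that activates antioxidant genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts (MEFs) of the 129S6/SvEvTac strain. The cells were wild type (WT) or knockout (KO) for GCN2, the kinase encoded by Eif2ak4 that senses uncharged tRNA when amino acids are scarce. Each genotype was kept for 24 h in complete DMEM or in DMEM lacking leucine. The labels give 6 samples, of which 4 are NRF2 libraries with a peak list each and 2 are input libraries from complete medium, 1 per genotype, for which no separate file was used here.

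Libraries were sequenced as single reads of 50 bp, per the labels' protocols. Alignment and peak calling tools were BWA 0.7.12, MACS2 2.1.0 and HOMER 4.7 on the mm10 genome build, per the submitters' processing notes, which do not state the settings. Peaks were called separately for each library against the complete-medium input of the same genotype, per the file headers, so the libraries without leucine were also set against an input from complete medium. The windows were 300 bp wide and were annotated with the nearest transcription start site (TSS) and a feature class by HOMER, per the file headers. The peak score is a whole number that the authors deposited with each peak. The lowest score was 13 in every list, and the column of the caller from which it was taken is not given in the sources used here. CpG and GC content are given by the authors as a fraction from 0 to 1 of the window. Scores were used only to rank or filter peaks within a list. Ranks in lists of different lengths do not measure a change in binding.

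The number of reads behind each list is unknown, so differences in sequencing depth between libraries could not be taken into account. Deeper libraries pass a fixed threshold at more sites, and a peak missing from a list fell below the authors' threshold, which does not show absence of binding. With 1 library per condition there are no replicates, no difference between lists has a replicate check, and no p-value is given. The 95% intervals for shares are exact Clopper-Pearson intervals and cover counting error only. Those for ratios of region counts also cover counting error only, and they treat regions as independent of each other. An NRF2 peak list does not measure whether Eif2ak4 was disrupted, so it does not check the knockout label.

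Peaks of 2 lists were called shared when they overlapped by at least 1 bp. The chance value was the mean share over 100 random placements of the peaks on the same chromosomes. Placement was uniform along each chromosome and ignored how well reads map and where chromatin is open. An excess over chance therefore need not come from NRF2 binding. All peaks were merged into regions, and each region was assigned to the lists that held a peak in it. A gene was counted as having a peak when a peak assigned to it by the authors' nearest-gene annotation lay within 10 kb of its TSS. Nearest-gene assignment gives each peak to 1 gene, so a neighbour of that gene gains no count from it. The recurrence of peaks by score used deciles of each list, with a chance value from 10 placements. This description was added after the lists were seen.

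The comparisons were leucine withdrawal against complete medium within each genotype and GCN2 KO against WT within each medium, which makes 4 comparisons. The comparisons, the rules for named genes, the gene lists and the alternatives, with 1 exception given below, were fixed before the data were examined. There were 10 lists with 374 entries, and a gene in several lists is an entry in each. The lists were NRF2 target genes, ATF4 and amino acid response genes, heme and iron genes, genes of the AP-1, CNC and small Maf families, autophagy and lysosome genes, proteasome subunit genes, cytosolic ribosomal protein genes, and genes typical of fibroblasts, of macrophages, and of neurons and hepatocytes. Symbols were matched to the GRCm38.p6 gene table, the same assembly as mm10, through the identifiers in the lists, and 373 entries matched. Each list's count was set beside 10000 random lists of the same size, drawn from 21896 protein-coding genes in 5 bins of gene length. The percentile describes that library only.

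Genes were named by 4 rules. These took the 10 regions in all 4 lists with the best mean rank within 10 kb of a TSS, the 10 highest-scoring peaks of each list with no overlap in the other list of a comparison, with 1 peak per gene, any member of a gene list with a peak within 10 kb, and Eif2ak4, Hmox1, Nqo1, Slc40a1, Slc48a1, Spic, Asns, Atf4 and Trib3. A few genes that meet these rules are not reported here, although the counts include them.

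Alternatives used the higher-scoring 50% of each list, equal list lengths of 2336 peaks, the main chromosomes without satellite and simple repeats, a reciprocal overlap of 50%, peak centres within 100 bp, peaks widened by 500 bp, distances to the TSS of 1 kb, 50 kb or any length, a promoter defined by distance, and a background of genes in any list. The heme and iron list without the genes it shares with the NRF2 target list was added after the data were seen. A planned search for the antioxidant response element in the peaks was not run, because no genome sequence was used here. The calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The overlap and gene list calculations were tested on simulated peaks, where planted and recovered values differed by at most 0.032 percentage points or regions and lists with no planted excess had a median percentile of 46.2.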

Results

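NRF2 binding sites were compared in MEFs that were WT or lacked the amino acid sensor GCN2, after 24 h with or without leucine. The 4 NRF2 lists held 2336 peaks for WT in complete medium, 5980 for WT without leucine, 3141 for GCN2 KO in complete medium and 4600 for GCN2 KO without leucine. Each list came from 1 library, so none of the differences below has a replicate check, and the read depth behind each list is unknown. Eif2ak4, the gene that encodes GCN2, had a single assigned peak, in the WT list without leucine, in intron 3 of 38 at chromosome 2, 118405935 to 118406235, 16973 bp from the TSS. The other lists held no peak assigned to Eif2ak4, and these lists do not measure the gene's disruption. All coordinates are mm10.

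NRF2 peaks lay within 10 kb of antioxidant genes and of both ferritin genes in every condition. Of the 50 NRF2 target genes, 27 had a peak within 10 kb of the TSS in WT cells in complete medium, 30 in WT cells without leucine, 21 in GCN2 KO cells in complete medium and 20 in GCN2 KO cells without leucine. Random lists of like gene length averaged 1.19, 3.29, 1.63 and 2.09 genes, and the observed counts lay at percentile 100 of the random lists in all 4 libraries. A set of 17 target genes had a peak in every list. It included Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, Nqo1, the quinone reductase, Gclc, the catalytic subunit of glutathione synthesis, Txnrd1, Prdx1, Prdx6 and Txn1 of the thioredoxin and peroxiredoxin systems, Me1, Gstm1, Ephx1, Aox1, the autophagy receptor Sqstm1 and Mafg, a small Maf partner of NRF2. The remaining genes of this set were Fth1 and Ftl1, the ferritin subunits that store iron, Slc48a1, a heme transporter, and Fech, which inserts iron into protoporphyrin to form heme. The heme and iron list shares 7 genes with the target list, among them Hmox1, Fth1, Ftl1, Slc48a1 and Fech, its only members with a peak in all 4 lists. Its counts of 8, 11, 7 and 8 of 40 genes, against random means of 0.944, 2.66, 1.29 and 1.67, were 3, 6, 2 and 3 of 33 without the shared genes, against random means of 0.771, 2.23, 1.06 and 1.37. These lay at percentiles 97.6, 98.7, 81.1 and 89.8, a comparison added after the data were seen.

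The merged peaks formed 14390 regions, and 256 of them (1.78%) were in all 4 lists, 96 of these within 10 kb of a TSS in every list. The site upstream of Ftl1, at chromosome 7, 45460842 to 45461142 in WT cells in complete medium, centred at -1106 bp relative to the Ftl1 TSS and annotated to a transcript end, ranked 2, 1, 1 and 5 in the lists in the order given above. A peak in intron 2 of 9 of Creld1 (chromosome 6, 113487314 to 113487614), in a window annotated to a repeat element, ranked between 2 and 5. Other sites of this group lay in intron 1 of 12 of the bromodomain gene Brd2, upstream of Gclc (chromosome 9, 77750588 to 77750888), at the Prdx1 promoter (chromosome 4, 116685295 to 116685595), in intron 1 of 2 of Slc48a1 (chromosome 15, 97786728 to 97787028), near Mir3076 and near the chemokine gene Ccl1. The Mir3076 site lay at -7540 bp relative to that TSS in WT cells in complete medium. It was annotated to intron 4 of 13 of another transcript, whose gene gained no count from it. A site at -3910 bp relative to the Gstp2 TSS was assigned to that gene, so its neighbour Gstp1, a member of the target list, was counted as having no peak. Hmox1 carried a pair of upstream peaks in each list. In WT cells without leucine these lay at chromosome 8, 75083836 to 75084136 and 75089559 to 75089859, both intergenic, with ranks 14 and 72. With a limit of 1 kb from the TSS, target genes with a peak numbered 11, 14, 10 and 9, and heme and iron genes 1, 2, 0 and 1.

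**Figure D1:**
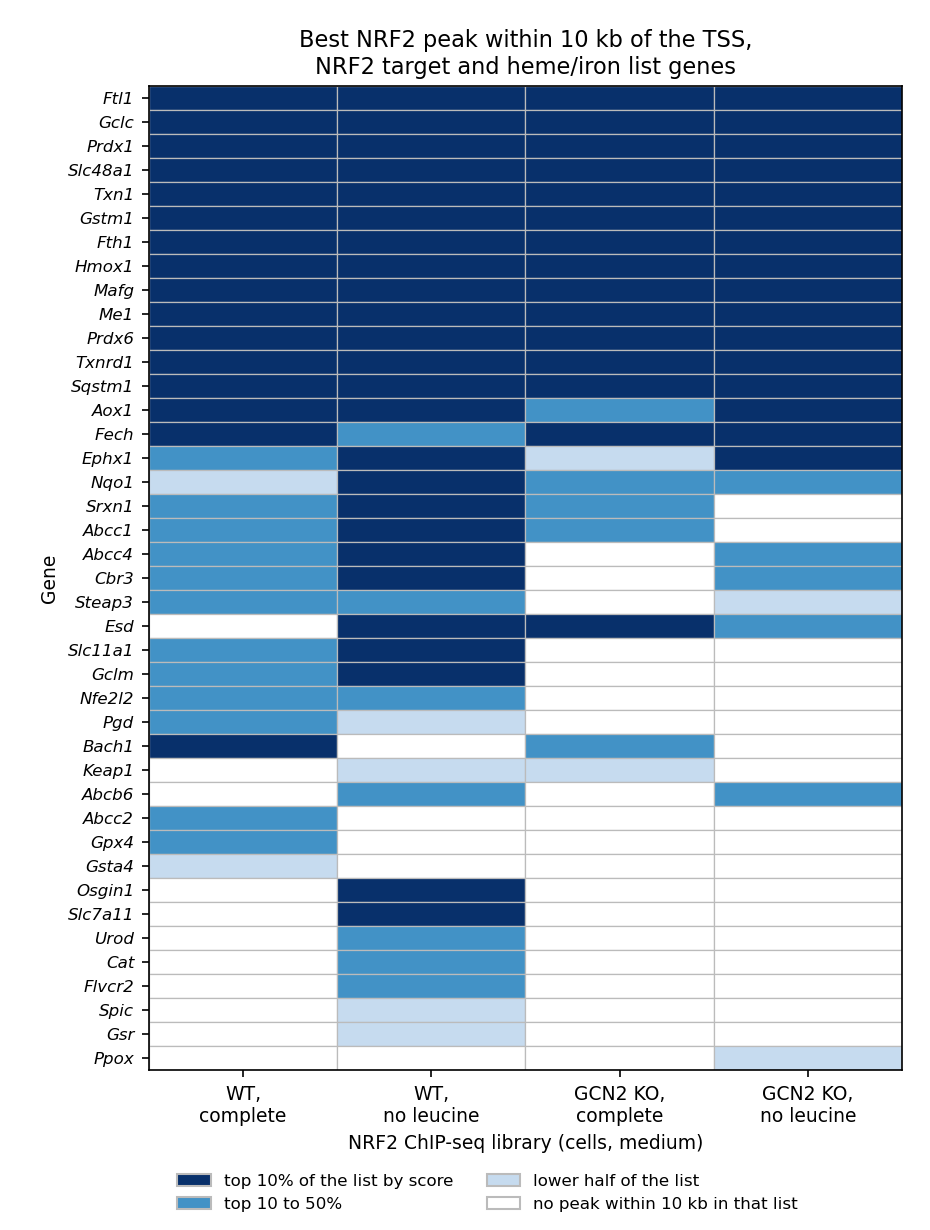
Reported genes of the NRF2 target list and the heme and iron list with a peak within 10 kb of the TSS in any list (vertical axis), in each of the 4 libraries (horizontal axis). The colour gives the place of the gene's best peak within that list by the authors' score, and white means no peak within 10 kb in that list. Ftl1, Gclc, Prdx1, Slc48a1 and Hmox1 are among the genes with a peak in the top 10% of all 4 lists, and Slc7a11 and Osgin1 have a peak in the WT list without leucine alone.

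Leucine withdrawal in WT cells was compared first, asking where NRF2 was bound when an amino acid was missing and GCN2 was present. NRF2 target genes with a peak numbered 27 of 50 with leucine and 30 of 50 without it, with 24 genes in both lists. Among the 24, the Pgd peaks were different sites, at -4038 bp relative to the TSS in complete medium and 1299 bp without leucine. The 6 that had a peak only without leucine were Slc7a11, the cystine transporter (intron 2 of 11, chromosome 3, 50438109 to 50438409, rank 373), Osgin1 (promoter, chromosome 8, 119436850 to 119437150, rank 252), Gsr, the glutathione reductase, Cat, the catalase, Keap1, the repressor of NRF2, and Esd. The 3 with a peak only in complete medium were Gsta4, Gpx4 and Abcc2. Heme and iron genes went from 8 to 11 of 40. Abcb6, a porphyrin transporter, Flvcr2, Urod and Spic, a transcription factor of iron-recycling macrophages, were added, and Bach1, a repressor that binds the same sites as NRF2, was in the complete-medium list alone (rank 178). Of the 41 ATF4 and amino acid response genes, Slc3a2 had a peak in complete medium, and Psat1, Slc7a11, Cars1 and Pck2 had one without leucine. These 4 genes lay at percentile 81.3 of random lists, and at 55.1 against a background of genes assigned a peak in any list. Atf4, Trib3 and Asns had no peak within 10 kb.

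The 2336 peaks of WT cells in complete medium included 535 (22.9%, 95% interval 21.2 to 24.7) that overlapped a peak of the longer list without leucine, against 0.272% by random placement. Of the 5980 peaks without leucine, 536 (8.96%, 8.25 to 9.72) overlapped the complete-medium list. The highest-scoring sites near a gene of the list without leucine and not of the complete-medium list lay at Rn45s, a ribosomal RNA gene, Hspb8, a small heat shock protein gene, Htatip2, Pitpnm2, 1600014C10Rik, Osgin1, Atp6v1f, Mir1929 and Neurl1a. Those of the complete-medium list alone lay at another position in Rn45s and at 4933417E11Rik, Slc14a2, Bach1, Hrsp12, Pxt1, LOC100503676, 4930503B20Rik, Pisd-ps3 and Grm4. Here and in the comparisons below, each name is that of the nearest TSS, up to 10 kb away. A site named for 1 list of a comparison lacked overlap with the other list compared, and may be in lists outside that comparison. The LOC100503676 and Cdc42bpg regions, for example, were in WT in complete medium and KO without leucine alone. The Socs3 sites of KO in complete medium and WT without leucine overlapped. Some named windows were annotated to repeat elements. The Atp6v1f and Mir1929 sites, at -9269 and -5927 bp relative to those TSSs, lay in introns of other transcripts. Ribosomal RNA genes occur in many copies, so reads of all copies may meet at the Rn45s position. With lists of equal length, target genes numbered 27 with and 27 without leucine, heme and iron genes 8 and 8, ATF4 and amino acid response genes 1 and 2, and 21.1% of the peaks without leucine were shared. In the higher-scoring 50% of each list the shared percentages were 37.8% and 14.8%.

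In GCN2 KO cells the same medium change left the number of NRF2 target genes with a peak at 21 of 50 with leucine and 20 of 50 without it, with 18 genes in both lists. Abcc4, a drug and metabolite exporter, and Cbr3, a carbonyl reductase, had a peak only without leucine, whereas Srxn1, the sulfiredoxin gene, Abcc1 and Keap1 had one only in complete medium. Slc7a11, Gclm, Gsr, Cat and Osgin1 had no peak within 10 kb in either KO list. Heme and iron genes numbered 7 and 8 of 40. Abcb6, Steap3 and Ppox were in the list without leucine alone, and Bach1 was among those in the complete-medium list alone. None of the 41 ATF4 and amino acid response genes had a peak within 10 kb in a KO list, where random lists averaged 1.24 and 1.65 genes and the count of 0 lay at percentiles 13.9 and 9.3, and at 6.89 and 3.82 against genes assigned a peak in any list. Within 50 kb, 3 and 2 of these genes had a peak.

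Of the 3141 KO peaks in complete medium, 429 (13.7%, 12.5 to 14.9) overlapped the list without leucine, against 0.370% by random placement, and 429 of the 4600 peaks without leucine (9.33%, 8.50 to 10.2) overlapped the complete-medium list. The highest-scoring sites of the complete-medium list and not of the list without leucine lay at Mir3082, the promoter of the translation elongation factor gene Eef1a1 (chromosome 9, 78481515 to 78481815, rank 40), Sfi1, Socs3, an inhibitor of cytokine signalling, Rn45s, Stub1, Mir155, Pkm and A530013C23Rik. Those of the list without leucine and not of the complete-medium list lay at Zfp36, which encodes an RNA-binding protein (chromosome 7, 28381419 to 28381719, rank 109), Sfi1, Dynlt1b, LOC100503676, Rn45s, Cdc42bpg, Ssc4d, 4930568G15Rik, Wrb and AI314180. The Sfi1 windows on chromosome 11 were adjacent, at 3193034 to 3193334 in complete medium and 3193347 to 3193647 without leucine, and missed the overlap only narrowly, so they need not be separate sites. Rn45s was named on both sides for different positions in the gene. In the higher-scoring 50% of each list the shared percentages were 21.5% and 14.7%, and with lists of equal length both were 15.8%. At equal lengths target genes numbered 19 with and 20 without leucine, which turns the direction of that small difference.

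GCN2 KO cells were then compared with WT cells in complete medium, to ask whether the sensor's loss went with a change in NRF2 binding when leucine was present. Fewer NRF2 target genes had a peak in KO cells, 21 against 27 of 50, with 19 genes in both lists. The 8 genes with a WT peak alone were Gclm, the regulatory subunit of glutathione synthesis (chromosome 3, 122245524 to 122245824, 5' UTR, rank 440), Nfe2l2, which encodes NRF2 itself (intron 1 of 4, chromosome 2, 75703797 to 75704097, rank 322), Pgd, Gsta4, Gpx4, Abcc2, Abcc4 and Cbr3. The 2 with a KO peak alone were Keap1 and Esd. Heme and iron genes numbered 8 in WT and 7 in KO. Slc11a1, a metal transporter of phagocytes (intron 2 of 14, chromosome 1, 74376457 to 74376757), and Steap3, an iron reductase, were in the WT list alone.

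Of the WT peaks, 364 of 2336 (15.6%, 14.1 to 17.1) overlapped a KO peak, and 364 of 3141 KO peaks (11.6%, 10.5 to 12.8) overlapped a WT peak, against 0.216% and 0.153% by random placement. The highest-scoring sites in the WT list alone lay at 9130015L21Rik, the splicing factor gene Srsf2 (promoter), Mest, Mvp, the major vault protein gene, 4933417E11Rik, Fam212a, Disp1, Dnmt3l, Cox20 and Pir. Those in the KO list alone lay at Mir3082, Adcy3, Dusp26, Slc20a1, Sfi1, Stub1, Clgn, Strn3 and Esd. In the higher-scoring 50% of each list the shared percentages were 26.0% and 19.4%. At equal list lengths the target gene counts were 27 in WT and 19 in KO.

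Without leucine, 30 of 50 NRF2 target genes had a peak in WT cells and 20 in GCN2 KO cells, and all of the latter were among the former. The 10 genes with a WT peak alone were Gclm, Slc7a11, Srxn1, Gsr, Pgd, Abcc1, Cat, Keap1, Nfe2l2 and Osgin1, so they held both glutathione reductase and the cystine transporter. Their WT ranks ran from 165 for Abcc1 to 5396 for Gsr. Heme and iron genes numbered 11 in WT and 8 in KO. Slc11a1, Flvcr2, Urod and Spic were in the WT list alone, Ppox in the KO list alone, and Hmox1, Fth1, Ftl1, Slc48a1, Fech, Abcb6 and Steap3 in both. The Steap3 peaks were different sites, at -310 bp relative to the TSS in WT and 2657 bp in KO. The Spic peak was intergenic at chromosome 10, 88690957 to 88691257, at -8084 bp relative to the TSS, with rank 3881 of 5980. Slc40a1, which encodes the iron exporter ferroportin, had no assigned peak in any of the 4 lists.

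Of the 5980 WT peaks without leucine, 476 (7.96%, 7.29 to 8.67) overlapped a KO peak, and 477 of 4600 KO peaks (10.4%, 9.50 to 11.3) overlapped a WT peak, against 0.217% and 0.284% by random placement. The highest-scoring sites in the WT list alone lay at Socs3, Mvp, Eef1a1, Rn45s, Slc11a1 (rank 132), 9130015L21Rik, Abcc1, Xkr8 and Bet1. Those in the KO list alone lay at Snx31, Kcnmb4, Zfp957, 4930503B20Rik, LOC100503676, Cdc42bpg, Strn3, Slc14a2, Wrb and AI314180. All of these KO windows except Zfp957, Slc14a2 and AI314180 were annotated to repeat elements. Among the WT windows this held for Xkr8 and Bet1. At equal lengths the shared percentage was 17.3% in both directions, and target genes numbered 27 in WT and 20 in KO. In the higher-scoring 50% of each list the shared percentages were 13.7% and 17.9%.

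Across the design, the number of regions confined to a single list was 1706 for WT in complete medium, 5226 for WT without leucine, 2562 for KO in complete medium and 3955 for KO without leucine. Together these made 13449 of 14390 regions (93.5%). Regions in both lists without leucine and in neither complete-medium list numbered 97, among them sites at Abcb6 (intron 1 of 18, chromosome 1, 75179268 to 75179568 in WT), Dynlt1b and Rn45s. Regions in both WT lists alone numbered 149 and included Mvp, 9130015L21Rik, Mest and Xkr8. Both KO lists alone shared 97 regions, including Strn3 and Ccn1, a matricellular protein gene listed under its older symbol Cyr61. Both complete-medium lists alone shared 23 regions, including Bach1. At equal list lengths the regions confined to both lists without leucine numbered 56, those to both WT lists 127, those to both KO lists 61 and those to both complete-medium lists 26.

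**Figure D2:**
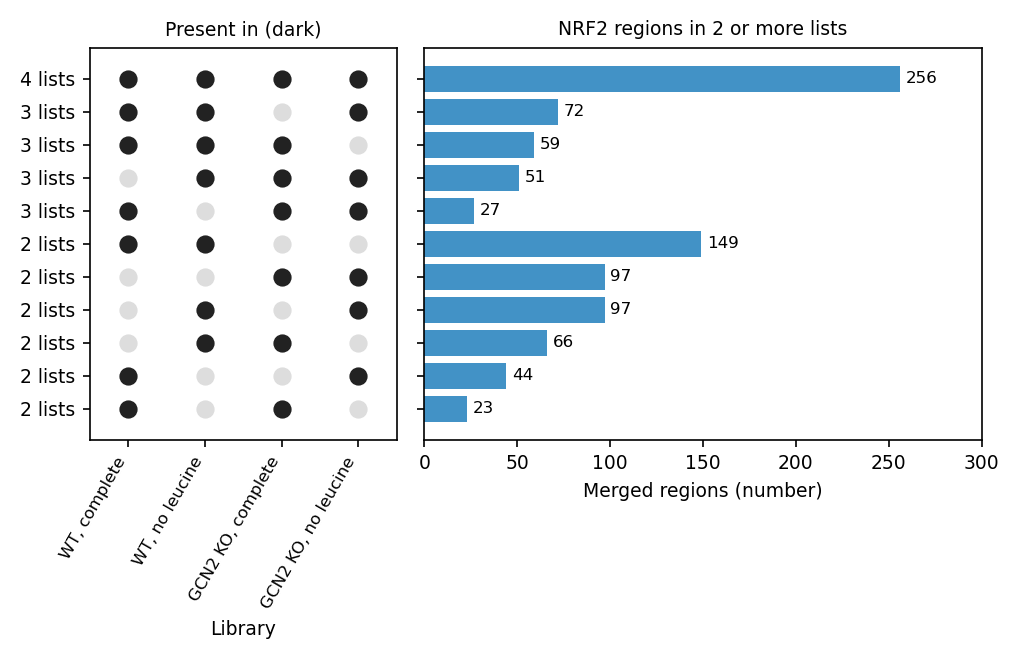
Number of merged NRF2 regions (horizontal axis) for each combination of 2 or more lists, with dark dots marking the lists that held a peak. The longest bar is the 256 regions in all 4 lists, followed by 149 regions in both WT lists alone.

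Recurrence followed the authors' score. In the highest score decile, 95.7% of WT peaks in complete medium overlapped a peak of any other list, as did 76.8% in WT without leucine, 85.4% in KO in complete medium and 79.8% in KO without leucine. In the lowest decile these shares were 6.87%, 1.34%, 3.18% and 4.57%, against chance values between 0.316% and 0.621%. Target genes lay mostly toward the upper end of the score range. Those with a peak above the middle score rank of their list numbered 25 of 27, 27 of 30, 19 of 21 and 20 of 20, in the same order. Ftl1 stood at the top of the lists. The Nqo1 promoter peak (chromosome 8, 107403525 to 107403825) ranked 2249 of 2336 in WT cells in complete medium. Nqo1 ranked 367 of 5980 in WT without leucine, 469 of 3141 in KO in complete medium and 696 of 4600 in KO without leucine.

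**Figure D3:**
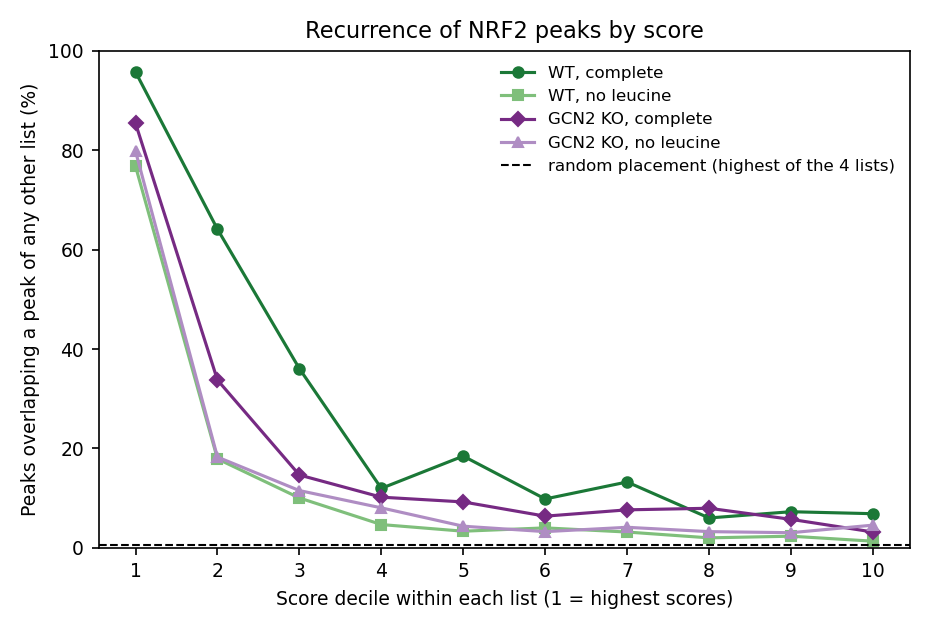
Percent of peaks that overlapped a peak of any other list (vertical axis) by score decile within each list (horizontal axis, 1 is the highest), with the dashed line at the highest chance value of the 4 lists, 0.621%. The share falls from between 76.8% and 95.7% in the highest decile to between 1.34% and 6.87% in the lowest.

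Promoter-TSS peaks made 2.70% (2.08 to 3.44) of the WT list in complete medium, 2.69% (2.30 to 3.13) of WT without leucine, 2.13% (1.66 to 2.70) of KO in complete medium and 1.54% (1.21 to 1.94) of KO without leucine. Intergenic peaks made 44.3% (42.2 to 46.3), 42.5% (41.2 to 43.8), 44.6% (42.9 to 46.4) and 49.3% (47.8 to 50.8), and intron peaks 44.6%, 44.5%, 44.3% and 40.8%. The KO list without leucine thus had the lowest promoter share and the highest intergenic share of the 4. Within 1 kb of a TSS on either side lay 4.71% (3.89 to 5.65), 5.28% (4.73 to 5.88), 3.72% (3.09 to 4.45) and 3.61% (3.09 to 4.19) of peaks. By that definition the interval of the KO list without leucine overlapped those of both complete-medium lists and lay below that of WT without leucine. In the promoter-TSS class its interval overlapped only that of KO in complete medium.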

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

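The tests of local copy number and of a loss particular to NRF2 target genes were written down before their results were seen, and the tests of weak peaks, leucine-set binding, list length, the common input and weaker sites were chosen after the result was seen.

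Several differences between lists pointed in opposite directions in the groups compared, and none of these was tested, since each list is 1 library. The KO list was longer than the WT list by 805 peaks in complete medium and shorter without leucine, a gap of 2185 between those differences. The leucine difference in NRF2 target genes was 3 in WT and -1 in KO, which differ by 4, and at equal list lengths the counts were 27 and 27 in WT and 19 and 20 in KO. Autophagy and lysosome genes with a peak numbered 2 in WT and 3 in KO in complete medium and 5 and 4 without leucine, a difference of 2 between the genotype effects, and at equal list lengths 2 and 3, and 3 and 4, so that KO was above WT by 1 in both media. Cytosolic ribosomal protein genes numbered 3 and 0 in WT with and without leucine and 0 and 1 in KO, which makes -4 for both the leucine and the genotype effect. At equal list lengths only the 3 in WT with leucine were left, and no opposite direction remained. Fibroblast genes numbered 0 and 3 in WT and 3 and 1 in KO, a difference of 5 for both effects, and at equal list lengths 0 and 1 in WT and 2 and 1 in KO, where the leucine effects still had opposite directions and the genotype effects did not. Neuron and hepatocyte genes numbered 3 and 4 in WT and 2 and 0 in KO, a difference of 3 between the leucine effects, and at equal list lengths 3 and 0 in WT and 2 and 0 in KO, lower without leucine in both genotypes.

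Peaks found in a single list made up 93.5% of regions. The lowest score decile recurred in another list at most 0.0717 times as often as the highest, in the list where this ratio was largest. Single-list peaks of low score may thus be weak sites near the calling threshold. In the decile just below the highest, 64.1%, 17.9%, 33.8% and 18.3% of peaks recurred, in the order WT complete, WT without leucine, KO complete and KO without leucine. Scores there ran from 46 to 100, above the lowest score of 13. Nearness to the threshold therefore need not account for the single-list peaks of that decile, which says nothing about those of lower score. For binding set by leucine in both genotypes, regions in lists of 1 medium were compared with regions in lists sharing neither medium nor genotype, with list sizes cancelling. That ratio was 0.768 (95% interval 0.424 to 1.39), and the interval is too wide to exclude a modest surplus. An effect of leucine in WT cells alone cannot be separated from the variation of 1 library.

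Regions in 2 lists of 1 genotype were more frequent than regions in lists sharing neither, with a ratio of 4.98 (3.14 to 7.88) in which list length and sensitivity cancel, which argues against these as the source. Calls near the threshold shared through the input common to a genotype are also disfavoured as the whole source, since the ratio was 3.46 (1.95 to 6.14) in the higher-scoring 50% of each list. It was 6.48 (1.79 to 23.4) in the lower-scoring 50%, so a part from such calls is not excluded. Of the same-genotype regions, 28.9% had another within 1 Mb, against 20.7% to 32.5% under permuted labels, and copy number stays open, because the bound set beforehand counted any value in that range against it although no share expected under altered copy number was computed. An effect of GCN2 on binding, a difference between cell populations unrelated to GCN2, and the shared input at strong peaks remain open, because each condition is 1 library and each genotype has 1 input.

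The NRF2 target list had 10 genes with a WT peak and no KO peak in either medium, and 0 the other way. Of 57 best WT peaks, 39 were found in the KO list of the same medium. That is 1.13 times the 34.4 found for WT peaks of like rank, with a 95% range of 27.7 to 41.2. The range takes the 24 genes counted in both media to move together. This cannot decide on a loss particular to target genes, because true target sites may recur more often than other peaks of like rank even after a loss. Target genes with a peak in both WT lists numbered 24, against 19 in both complete-medium lists and 20 in both lists without leucine. Genes without a KO peak had median WT ranks of 521 in complete medium and 1094 without leucine, against 56 and 52.5 for genes with one, and the smaller of these ratios was 9.30. The missing KO peaks may thus be weaker sites that fell below the threshold, as other WT peaks of like rank did. Whether binding in KO cells was lower in general, or the KO libraries were less sensitive, remains open.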

How the results depend on the processing

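All alternatives were planned except the heme and iron list without genes shared with the NRF2 target list, added after the data were seen, which left 3, 6, 2 and 3 genes. A value counted as kept when a percentage stayed within the 95% interval of the reported one, or a count within 1.5 times. Restricting the lists to the main chromosomes without satellite and simple repeats kept all 37 main values. It left 2315, 5934, 3107 and 4557 peaks, so few were removed that little change was possible, and repeats of other classes stayed in. A reciprocal overlap of 50% kept 8 shared percentages, and centres within 100 bp kept 9 region counts. With that centre rule, regions in both KO lists fell from 97 to 75 and those in both lists without leucine from 97 to 79. The number of regions in all 4 lists ranged from 219 to 258. The order of target gene counts, WT above KO in each medium, held under every setting run, but the leucine difference in WT was 0 at equal lengths. In the higher-scoring 50% of each list, which is shorter by construction, the lists held 1168, 2990, 1570 and 2300 peaks. Shared percentages were 37.8 and 14.8 for WT, 21.5 and 14.7 for KO, 26.0 and 19.4 in complete medium and 13.7 and 17.9 without leucine. Single-list regions numbered 657, 2375, 1115 and 1790, regions in both KO lists 48, and ATF4 list genes in WT without leucine 2. At equal lengths the shared percentages were 21.0 and 21.1 for WT, 15.8 and 15.8 for KO, 15.1 for KO peaks in complete medium, and 17.3 and 17.3 without leucine. Regions confined to WT without leucine numbered 1703, to KO without leucine 1800, to both lists without leucine 56 and to both KO lists 61, with 2 ATF4 list genes in WT without leucine. Widening peaks by 500 bp gave 14.9 for KO in complete medium, 10.3 for KO without leucine, and 8.88 and 11.5 between genotypes without leucine. Within 1 kb of a TSS lay 4.71, 5.28, 3.72 and 3.61% of peaks, against the smaller promoter class. Counting list genes within 1 kb left 11, 14, 10 and 9 NRF2 targets, 1, 1, 0 and 0 ATF4 list genes, and 1, 2, 0 and 1 heme and iron genes. ATF4 list genes within 50 kb numbered 2, 7, 3 and 2, and at any distance 6, 10, 6 and 4. Apart from shorter lists and other distances, the cause was not tested. The motif alternatives were not run. Unknown depth limits every count. Against a background of genes assigned a peak in any list, 27 of 40 list percentiles moved by more than 1 point, while those of the NRF2 target list and the full heme and iron list stayed at 99.87 or above.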

Other observations

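The gene list counts, their percentiles and their alternatives were planned, and the chromosome X values were chosen after the lists were seen. Genes of the AP-1, CNC and small Maf families with a peak within 10 kb numbered 3, 4, 2 and 3 of 24, in the order WT complete, WT without leucine, KO complete and KO without leucine. Mafg had a peak in all 4 lists, Nfe2l2 in both WT lists, Bach1 in both complete-medium lists and Fosl1 in both lists without leucine, while Maff and Nfe2l3 had one in a single list. These counts lay at percentiles 99.1, 96.7, 90.7 and 96.0 of random lists, and at 95.1, 76.4, 72.1 and 81.3 against a background of genes assigned a peak in any list. Autophagy and lysosome genes numbered 2, 5, 3 and 4 of 37, with Sqstm1 and Tfe3, a regulator of lysosomal genes, in all 4 lists, at ranks 116 and 65 in WT cells in complete medium. Ctsd, which encodes the lysosomal protease cathepsin D, had a peak in every list except WT in complete medium.

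Proteasome subunit genes with a peak numbered 0, 4, 0 and 1 of 31 in the same order, with Psmd7 in both lists without leucine and Psmc2, Psmc3 and Psmd3 in WT without leucine. The Psmd7 peaks were different sites, at -9568 bp relative to the TSS in WT and 241 bp in KO. With lists of equal length the counts were 0, 0, 0 and 1. Cytosolic ribosomal protein genes numbered 3, 0, 0 and 1 of 44, namely Rpl10a, Rpl19 and Rps19 in WT in complete medium and Rps14 in KO without leucine. Fibroblast genes numbered 0, 3, 3 and 1 of 37, and Ccn1 was in both KO lists. Macrophage genes numbered 3, 5, 1 and 3 of 33, with 12 genes in any list and none in more than 1. Neuron and hepatocyte genes numbered 3, 4, 2 and 0 of 36, and only Grin2b was in more than 1 list. Its peaks were different sites, at -1055 bp relative to the TSS in WT in complete medium and -4428 bp in WT without leucine. The macrophage list lay at percentiles 97.7, 96.6, 54.0 and 90.0, and the neuron and hepatocyte list at 96.3, 86.0, 78.4 and 10.5. Against genes assigned a peak in any list these percentiles were 94.8, 91.2, 40.6 and 80.6, and 89.3, 56.2, 56.3 and 3.35. At equal list lengths macrophage genes numbered 3, 1, 1 and 1, and neuron and hepatocyte genes 3, 0, 2 and 0.

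Chromosome X held 6 of 2328 WT peaks on the main chromosomes in complete medium (0.258%, 95% interval 0.0946 to 0.560). The WT list without leucine held 21 of 5965 there (0.352%, 0.218 to 0.538). In KO cells the counts were 12 of 3132 in complete medium (0.383%, 0.198 to 0.668) and 35 of 4581 without leucine (0.764%, 0.533 to 1.06). The chromosome makes up 6.49% of the length and 4.47% of the protein-coding genes. Each list was also split at its middle rank by score. In the higher-scoring part the shares were 0.517%, 0.537%, 0.511% and 0.568%, in the same order. In the lower-scoring part they were 0%, 0.167%, 0.255% and 0.960%. The difference between lists thus lay among the lower-scoring peaks. Of the regions in all 4 lists, 4 of 253 (1.58%) lay on chromosome X, among them the site in intron 2 of 9 of Tfe3.

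Regions confined to WT without leucine and KO in complete medium numbered 66, and those confined to WT in complete medium and KO without leucine 44.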
